A study of Homo sapiens and Mus musculus with 27 samples.

How the data were processed

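The analysis started from gene-level read counts as deposited by the authors, in 1 table for each dataset with a column for each of its 9 libraries. According to the submitters' processing notes and library descriptions, poly(A) RNA from Trizol extracts was sequenced as paired 150-base reads on a NovaSeq instrument, and reads were counted per gene with featureCounts 2.0.1 and summarised with MultiQC 1.11, on the GRCh38 build for human and the GRCm38 build for mouse. The aligner and the gene annotation version were not given in the sources used here. Every value in the tables was a whole number, and 56.9% to 66.1% of counts between 1 and 20 were even, so read mates appear to have been counted singly in part and the counts overstate the number of fragments. Columns were matched to libraries through the titles and column names, with no column left over. 1 vehicle tumour of 4T1 carries the species and cell line of another dataset in some of its other labels. It was kept as a 4T1 tumour because its title, library name and table column say so.

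Human features were named through an Ensembl identifier table, which gave a symbol to 61481 of 78932 features. The rest held 0.203% of counts in HCC1937 and 0.0857% in MDA-MB-231. Human gene positions are those of GENCODE release 29 on GRCh38, matched by identifier. The mouse table held 25239 symbols, which were used as they stood, without positions. 42 gene lists (pathways, complexes and cell type markers) were written down from general knowledge before the data were examined, together with the comparisons, the alternatives and the rule for named genes. Of the list members 626 of 628 were found in the human tables and 614 of 632 in the mouse table.

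Each dataset was fitted on its own with edgeR 4.0.16 in R 4.3.3, over its 9 libraries with 1 coefficient per group. Genes were kept by the filterByExpr function, libraries were scaled by TMM factors, and quasi-likelihood F tests compared the groups. The p-values were adjusted over all tested genes of a comparison by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Log2 CPM values used a prior count of 2, while log2 fold changes used the default prior count of edgeR. SE is the absolute log2 change divided by the square root of F. Common biological coefficients of variation were 0.339 in HCC1937, 0.204 in MDA-MB-231 and 0.316 in 4T1. Levels are CPM with TMM scaling.

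Lists with at least 3 tested members were tested with camera from limma 3.58.1, with its preset correlation between genes of 0.01, and were called at an adjusted p under 0.05 over the lists of a comparison. The same test with the correlation estimated from the data is given beside each call, and a list's members were also adjusted over that list alone. A list's level in a library is the mean log2 CPM of its members. Where the median change of a list and its test differ in sign the list was not called.

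Named genes followed a rule. Against vehicle these are the 8 largest rises and 8 largest falls among genes with a symbol that is neither a numbered locus nor a pseudogene, that were called, that reached 5 CPM on average in the higher group, and whose 3 treated libraries all lay on one side of the 3 vehicle libraries. Between treated arms the numbers are 5 and 5. From each list described come the 2 to 4 called members with the smallest p, or the 2 with the highest CPM where fewer than 2 were called. PSMB5, CXCR4, B2M, CD274, HMOX1, HSPA1A, SLC31A1 and MT2A (Mt2 in mouse), and Cd8a, Gzmb and Ifng in 4T1, are given whatever their result. Results for some genes and 1 list that the rule picks are not reported here. Genes outside this rule are said to be chosen after their values were seen. The rule gave no rises or falls for HCC1937 AMD3100 against vehicle, for the treated arms of MDA-MB-231 or for 4T1, where no gene was called.

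Each count of called genes, each called list and each named gene was run again with DESeq2 median-of-ratios scaling, without the low-count filter, with the replicate number in the model, with the compared groups fitted alone, and without each library in turn. Counts and named genes were also run with DESeq2 1.42.0 and limma-voom, and counts at a 2-fold change or an adjusted p under 0.01. Alternatives that leave out HCC1937 AMD3100 replicate 1 from comparisons it is not part of, that correct HCC1937 for GC content and transcript length (20 and 5 bins), or that put the B cell marker level of each tumour in the 4T1 fit were added after the data were seen. For each comparison the 6 libraries were also split in all 10 ways into groups of 3. For the difference between the human lines, 40 labellings of the treated libraries were drawn.

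The agreement of arms that share a vehicle group was set against 10 simulated draws with no effect, with random seed 11. The method was also tested on counts simulated with the fitted vehicle means and spread of each dataset, in which known genes were multiplied or divided. At 1.5-fold, 2-fold and 4-fold it recovered 0%, 18.5% and 65.6% of changed genes with the spread of HCC1937, 9.84%, 44.6% and 86.2% with that of MDA-MB-231, and 3.08%, 51.6% and 76.6% with that of 4T1. False calls were 3.70%, 3.19% and 6.74% of all calls. Only 61 to 65 genes per fold size were changed among 15294 to 18231 tested. Recovery depends on that share, so these values do not describe a comparison in which many genes change. The spread of HCC1937 was that of a fit with AMD3100 replicate 1. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.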

Results

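RNA was sequenced in 27 libraries that form 9 groups of 3 replicates, with 3 groups in each of 3 datasets. HCC1937, a human breast cancer cell line, was given vehicle, 10 µM TM or 10 µM AMD3100. MDA-MB-231, a second human breast cancer line, was given vehicle, 10 nM bortezomib with 10 µM TM, or 10 nM bortezomib with 10 µM AMD3100. The third dataset came from tumours of 4T1, a mouse mammary carcinoma line, grown in Balb/c mice. These mice received vehicle, or 1 mg/kg bortezomib every 4 days combined with either 0.05 mg/ml TM in the drinking water or 5 mg/kg AMD3100 every 2 days. Bortezomib inhibits the proteasome by binding its PSMB5 subunit, and AMD3100 blocks the chemokine receptor CXCR4. TM is used here as a name only, because the labels do not expand it. Total counts per library ran from 35981504 to 43973262 in HCC1937, from 40389469 to 50283398 in MDA-MB-231 and from 38407536 to 50735374 in 4T1. No group received bortezomib alone, so in MDA-MB-231 and 4T1 the part of bortezomib cannot be separated from that of its partner. Levels are given as means ± SD of CPM (counts scaled by library size) over the 3 libraries of a group, and fold changes are on the log2 scale with their standard errors (SE). Titles call the replicates biological, but where those of the cell lines came from was not stated, so the p-values measure only the spread between these samples.

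HCC1937 cells under TM were compared with vehicle to ask which genes differ with TM alone. GDF15, a secreted stress cytokine (ENSG00000130513, GRCh38 chromosome 19, 18374731 to 18389176), rose from 36.2 ± 2.22 to 636 ± 20.99 CPM (log2 4.14, SE 0.41, adjusted p = 0.00110). CDKN1A, which encodes the cell cycle inhibitor p21, rose from 47.8 ± 1.90 to 457 ± 20.8 CPM (log2 3.26, SE 0.18, adjusted p = 8.97e-05). SPRY4, an inhibitor of growth factor signalling, rose from 0.692 to 7.76 CPM and LSMEM2 from 0.805 to 8.94 CPM. Among the falls, HPD, an enzyme of tyrosine breakdown, went from 600.1 ± 16.2 to 145 ± 2.29 CPM (log2 -2.05, SE 0.19, adjusted p = 0.000790). TXNIP, which binds thioredoxin, fell from 29.2 to 4.37 CPM. HMMR, a hyaluronan receptor of the mitotic spindle, fell from 35.2 to 5.80 CPM and CA9, a carbonic anhydrase, from 7.11 to 1.17. CHRND, HSD17B8, ENTPD2 and TEX19 fell, with log2 changes of -2.38, -2.75, -2.49 and -3.09. The greatest fitted rises were those of SNORD3C (7.49), SNORD3B-1 (7.36), SNORD3A (6.22) and RNVU1-26 (6.22). These are small nuclear or nucleolar RNAs that lack a poly(A) tail and share reads with near-identical copies, so their values are uncertain. The feature named DHRSX (4.24) shares its symbol with another feature, varied from library to library (16.1 ± 14.9 CPM under TM) and is uncertain as well. RNVU1-26 (5.65 to 6.82), LSMEM2 (3.18 to 3.92) and TEX19 (-3.32 to -3.00) did not pass with any 1 of the 6 libraries left out, nor DHRSX without vehicle 1 (3.97), vehicle 2 (3.90) or TM 3 (3.13). limma-voom called neither TEX19 (-3.11) nor DHRSX (4.12).

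Of 33 gene lists tested with camera, 6 passed in the TM comparison, and with an estimated correlation between genes 1 of them still did. The cell cycle list had a median log2 change of -0.25, with 7 of 32 members falling (11 adjusted over the list alone) and none rising (adjusted p = 5.27e-06; adjusted p = 0.0318 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, fell from 175 ± 5.89 to 84.1 ± 4.82 CPM and MKI67, a proliferation marker, from 133 ± 1.48 to 82.1 ± 0.704 CPM. In the apoptosis list, CDKN1A and GADD45A, a DNA damage response gene that went from 39.8 to 101 CPM, were the 2 of 20 members that rose (5 adjusted over the list alone; median 0.54, adjusted p = 9.58e-06; adjusted p = 0.101 with an estimated correlation). The list of ATF4 targets of the integrated stress response had 7 of 22 members rising and 1 falling (11 and 1 adjusted over the list alone; median 0.43, adjusted p = 1.68e-05; adjusted p = 0.281 with an estimated correlation). SESN2, a stress-induced regulator of growth, rose from 19.2 to 42.4 CPM and NUPR1 from 5.70 to 15.8, while ALDH1L2, a mitochondrial folate enzyme, fell from 29.1 to 13.4. In the immunoproteasome list, 3 of 5 members fell (4 adjusted over the list alone; median -0.67, adjusted p = 6.5e-05; adjusted p = 0.101 with an estimated correlation). PSMB9, an interferon-inducible catalytic subunit, fell from 21.999 ± 2.58 to 8.13 ± 0.898 CPM, and the activator subunits PSME1 and PSME2 changed by -0.67 and -0.57. Replication-dependent histones, whose mRNAs lack a poly(A) tail and share reads, had 2 of 10 members falling, as adjusted over the list alone too (median -0.87, adjusted p = 0.00305; adjusted p = 0.212 with an estimated correlation). Their examples were H2BC12 (95.2 to 49.2 CPM) and H2AC6 (26.05 to 11.5). CD14 and CSF1R, which monocytes express, were the 2 of 4 macrophage marker genes that rose (2 adjusted over the list alone; median 0.85, adjusted p = 0.0223; adjusted p = 0.281 with an estimated correlation), at 4.99 and 10.1 CPM under TM. GADD45A (1.29 to 1.37), PSME1 (-0.71 to -0.65), PSME2 (-0.61 to -0.57) and CSF1R (0.65 to 0.81) did not pass with any 1 of the 6 libraries left out. CD14 passed without TM replicate 3 but not without any other (1.62 to 1.78). All of these fits kept AMD3100 replicate 1. With that library kept out instead, 71 named genes of this comparison kept their result and 5 gained a call. Without the low-count filter, PSME2 (-0.52) and CSF1R (0.81) did not pass. The macrophage list did not pass without AMD3100 replicate 1 (median 0.85), with vehicle and TM fitted alone (0.86) or without the low-count filter (0.13).

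Other lists did not pass, though some members did. Proteasome subunits had 1 of 33 members falling (median 0.063, adjusted p = 0.408), and PSMB5 was at 198 ± 5.34 CPM with vehicle and 214 ± 8.32 with TM (adjusted p = 0.823). NRF2 antioxidant targets had 4 rises and 1 fall among 20 (7 and 3 adjusted over the list alone; median 0.18, adjusted p = 0.0627, and 0.0484 with median-of-ratios scaling), among them SLC7A11, a cystine transporter, which rose from 17.7 to 39.1 CPM. Of the 22 type I interferon response genes 3 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.084, adjusted p = 0.159), with ISG15, a ubiquitin-like protein, rising from 33.7 to 80.8 CPM. In the copper handling list (median -0.019, adjusted p = 0.769), the copper importer SLC31A1 rose from 79.1 ± 2.08 to 126 ± 2.62 CPM and the exporter ATP7B fell from 25.9 ± 1.95 to 13.4 ± 1.24. The lipoylation list had 2 falls and 1 rise among 13 (3 and 1 adjusted over the list alone; median -0.28, adjusted p = 0.113), and LIAS, which makes lipoic acid, fell from 14.3 to 7.05 CPM. Heat shock genes had 2 rises and 2 falls among 20 (3 and 6 adjusted over the list alone; median -0.21, adjusted p = 0.173), with the small chaperone HSPB8 at 37.8 and then 77.99 CPM. CXCR4 was at 94.2 ± 7.53 CPM with vehicle and 105 ± 3.33 with TM (adjusted p = 0.431). B2M was at 212 and 209.8 (0.974), HMOX1 at 52.99 and 90.4 (0.142), HSPA1A at 567 and 322 (0.0798) and MT2A at 106 and 134 (0.358). CD274, which encodes PD-L1, had too few reads to test: 2, 2 and 0 counts with vehicle and 13, 7 and 12 with TM. Of the genes given here as rising, ISG15 (1.21 to 1.26) and SLC31A1 (0.64 to 0.67) passed with TM replicate 3 left out but not with any other 1 of the 6 libraries left out. With vehicle and TM fitted alone, HMOX1 (0.77), HSPA1A (-0.81), MT2A (0.34), CXCR4 (0.16) and PSMB5 (0.11) passed. Without the low-count filter and in DESeq2, HMOX1 (0.82 and 0.80) and HSPA1A (-0.76 and -0.79) did too.

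In all, edgeR called 576 genes higher and 800 lower under TM among 19461 tested, 1376 together at an adjusted p under 0.05. The balance of directions turned without the low-count filter, at 663 higher and 576 lower. The spread in this fit is shared with the AMD3100 libraries. Without AMD3100 replicate 1, in which mitochondrial genes held 19.9% of counts against 10.5% to 11.6% in the other 8 libraries, 3951 genes were higher and 4367 lower, 8318 in all, and with vehicle and TM fitted alone the number was 8336. Leaving out 1 library at a time gave 462, 440 and 444 calls without vehicle replicates 1, 2 and 3 and 442, 406 and 461 without TM replicates 1, 2 and 3.

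**Figure D1:**
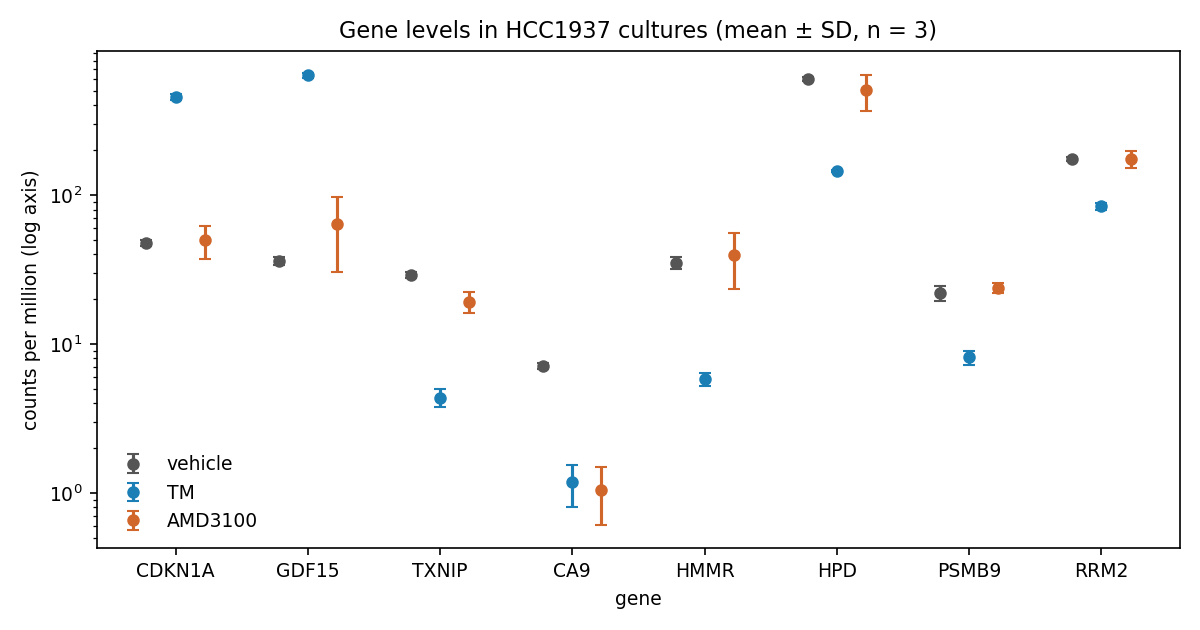
CPM of 8 genes in HCC1937, on a log axis. Points are group means, bars are SD of n = 3 libraries per group, and colours mark vehicle, TM and AMD3100. Single libraries are not drawn. CDKN1A rose from 47.8 CPM with vehicle to 457 with TM and was at 49.8 with AMD3100, while HPD fell from 600.1 to 145 with TM.

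HCC1937 cells under AMD3100 were compared with vehicle to ask the same of AMD3100 alone. No single gene passed in edgeR, so values are given without a direction. CXCR4, the receptor that AMD3100 blocks, was at 94.2 ± 7.53 CPM with vehicle and 84.7 ± 3.57 with AMD3100 (log2 -0.15, SE 0.095, adjusted p = 0.882). SLC7A5, an amino acid transporter, was at 6849 ± 145 and 6339 ± 1697 CPM (0.905), HSPA5, the main chaperone of the endoplasmic reticulum, at 814 ± 11.7 and 698 ± 7.13 (0.882), and the histone H2BC12 at 95.2 ± 1.93 and 70.7 ± 2.97 (0.882). PSMB5 was at 189 ± 47.6 CPM under AMD3100, B2M at 189 ± 35.6, SLC31A1 at 97.1 ± 14.1, HMOX1 at 43.8 ± 18.01, HSPA1A at 431 ± 155 and MT2A at 106 ± 26.6. CD274 had 0, 5 and 4 counts. HSPA5 (-0.19), H2BC12 (-0.40) and SLC31A1 (0.19) passed without AMD3100 replicate 1. The changes of PSMB5 (0.14), SLC7A5 (0.11), HMOX1 (0.049) and B2M (0.0044), negative with that library, were positive without it. That of MT2A was negative without vehicle 2 (-0.048) or AMD3100 2 (-0.16) or 3 (-0.064). In AMD3100 replicate 1, mitochondrial genes held 19.9% of counts against 10.5% to 11.6% in the other 8 libraries, and ribosomal RNA 3.05% against 0.626% to 0.698%. That library had a count for 20639 genes, where the other 8 had at least 29335.

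As sets, 6 of 33 lists passed under AMD3100, none of them with an estimated correlation, and no member of any passed on its own over all genes. The ATF4 list had a median of 0.22, with 1 of 22 members passing when adjusted over the list alone (adjusted p = 8.6e-05; adjusted p = 0.414 with an estimated correlation). Without AMD3100 replicate 1, 16 of its members rose (adjusted p = 3.24e-35), but without AMD3100 replicate 2 or 3 the list did not pass (medians 0.068 and 0.080). Histones (-0.57; 1 of 10 adjusted over the list alone; adjusted p = 0.000434, or adjusted p = 0.362 with an estimated correlation) and hypoxia and glycolysis genes (-0.12; 1 of 21 adjusted over the list alone; 0.00516, or adjusted p = 0.414 with an estimated correlation) were shifted lower. So were MHC class I genes (-0.22, 0.00516, or adjusted p = 0.521 with an estimated correlation), though with a median of -0.044 and adjusted p = 0.224 without AMD3100 replicate 1. NRF2 targets (0.11; 1 of 20 adjusted over the list alone; 0.0233, or adjusted p = 0.414 with an estimated correlation) did not pass without vehicle 1 (0.10) or 3 (0.085) or AMD3100 2 (0.12) or 3 (0.11). Endoplasmic reticulum chaperones (-0.20, 0.0447, or adjusted p = 0.521 with an estimated correlation) did not pass with any 1 of the 6 libraries left out (medians -0.26 to -0.084) or with median-of-ratios scaling (-0.19), nor NRF2 targets without the low-count filter (0.096).

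The count of 0 in edgeR stood beside 951 genes at an unadjusted p under 0.05, 16 called by DESeq2 and 0 by limma-voom. edgeR called 1099 genes higher and 562 lower, 1661 in all, without AMD3100 replicate 1.

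AMD3100 and TM, both given alone, were set side by side in HCC1937, where the direct comparison ran from TM to AMD3100. HMMR was higher with AMD3100, at 39.6 ± 16.1 CPM against 5.80 ± 0.576 with TM (log2 2.77, SE 0.26, adjusted p = 0.000953), as were HSD17B8 (2.74), TEX19 (2.83), CELF5 (2.39) and ENTPD2 (2.15). CDKN1A was lower with AMD3100, at 49.8 ± 12.3 against 457 ± 20.8 CPM (log2 -3.20, SE 0.18, adjusted p = 0.000154). The greatest negative changes were those of SNORD3B-1 (-6.42), SNORD3C (-6.35), SNORD3A (-4.20), LSMEM2 (-3.99) and DHRSX (-3.48), values that are uncertain for the small RNAs and DHRSX. CXCR4 was at 84.7 CPM with AMD3100 and 105 with TM (adjusted p = 0.0835), SLC31A1 at 97.1 and 126 (0.0793) and HMOX1 at 43.8 and 90.4 (0.0501). Without AMD3100 replicate 1, CXCR4 (-0.32), SLC31A1 (-0.48) and HMOX1 (-0.72) passed, as HMOX1 did without AMD3100 replicate 3 (-1.27). Calls were lost for TEX19 without any 1 of the TM libraries or AMD3100 2 or 3 (2.48 to 3.06), and for CELF5 without any 1 of the TM libraries (2.21 to 2.50). Those of LSMEM2 (-4.25 to -3.94) and DHRSX (-3.82 to -2.37) were lost without any 1 of the TM libraries or AMD3100 3. With the arms fitted alone these 4 and ENTPD2 (2.17) did not pass, and limma-voom did not call TEX19 (2.53), CELF5 (2.09) or DHRSX (-3.22). HMOX1 passed in DESeq2 (-1.06) and limma-voom (-1.14), with median-of-ratios scaling (-1.06) and without the low-count filter (-1.09).

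Of 33 lists, 7 passed between these arms and 1 of them with an estimated correlation. Cell cycle genes were higher with AMD3100, with 7 of 32 members passing (13 adjusted over the list alone; median 0.34, adjusted p = 3.08e-06; adjusted p = 0.0289 with an estimated correlation), such as RRM2 (84.1 to 176 CPM) and TOP2A, a DNA topoisomerase (128 to 232). Apoptosis genes were lower (2 of 20 members, 5 adjusted over the list alone; median -0.52, adjusted p = 1.41e-05; adjusted p = 0.149 with an estimated correlation), these being CDKN1A and GADD45A. The immunoproteasome list was higher (2 of 5, 4 adjusted over the list alone; median 0.64, adjusted p = 0.000656; adjusted p = 0.153 with an estimated correlation), with PSMB9 at 8.13 ± 0.898 and 23.9 ± 1.82 CPM and PSME1 at 60.8 and 94.5. Lower lists also included the interferon-γ response (-0.75, 2 of 8 members, 4 adjusted over the list alone, adjusted p = 0.0367; adjusted p = 0.235 with an estimated correlation), through IRF1 and GBP2. Macrophage (-1.28, 1 of 4, 4 adjusted over the list alone, adjusted p = 0.0155), neutrophil (-2.38, 0 of 4, 2 alone, 0.0428) and skeletal muscle markers (-1.21, 1 of 6, 1 alone, 0.0428) were lower too, with adjusted p = 0.485, 0.640 and 0.642 with an estimated correlation. Without AMD3100 replicate 1, whose mitochondrial share was 19.9%, none of these last 4 lists passed (medians -0.55, -0.90, -2.31 and -0.69), and without the low-count filter macrophage (-0.28) and muscle markers (-0.90) did not. Calls were lost without any 1 of the TM libraries for TOP2A (0.83 to 0.89) and GADD45A (-1.41 to -1.38), without these or AMD3100 3 for IRF1 (-0.67 to -0.60) and GBP2 (-3.70 to -3.46), and without these or AMD3100 2 or 3 for PSME1 (0.52 to 0.67). None of these 5 genes passed with the arms fitted alone (TOP2A 0.87, GADD45A -1.39, IRF1 -0.61, GBP2 -3.61 and PSME1 0.66).

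edgeR called 898 genes higher and 701 lower with AMD3100 than with TM, 1599 in all, where limma-voom called 827 higher and 861 lower. The edgeR number was 7442 without AMD3100 replicate 1, 1026 and 1435 without AMD3100 replicates 2 and 3, and 395, 394 and 373 without TM replicates 1, 2 and 3. It was 252 with the arms fitted alone and 725 with a replicate block, while DESeq2 called 2529.

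MDA-MB-231 cells given bortezomib with TM were compared with vehicle to ask what this combination changes. HSPA1A, an inducible heat shock protein, rose from 27.02 ± 4.93 to 2006 ± 392 CPM (log2 6.21, SE 0.20, adjusted p = 1.85e-09) and GABARAPL1, an autophagosome protein (ENSG00000139112, GRCh38 chromosome 12, 10212458 to 10223130), from 4.30 ± 0.331 to 397 ± 16.6 CPM (log2 6.53, SE 0.11, adjusted p = 1.51e-11). AKR1B10, an aldo-keto reductase, HSPA6, GCNT3, HKDC1, GADD45G and HSPA1B rose by log2 changes of 6.71, 6.63, 6.36, 6.30, 6.03 and 5.84. HSPA1A and HSPA1B are near-identical in sequence and HSPA6 resembles them, so how their reads divide is uncertain. The mucin MUC5AC fell from 23.1 ± 8.11 to 0.404 ± 0.0450 CPM (log2 -5.82, SE 0.36, adjusted p = 1.99e-07) and NOG, an antagonist of bone morphogenetic proteins, from 12.9 to 0.272. IGFBP1, SMAD6, FOXQ1, SPRY1, ADGRF1 and ATOH8 changed by -4.41, -4.36, -4.21, -4.21, -4.19 and -3.90.

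With bortezomib and AMD3100, the rule for named genes picked these 16 again. HSPA1A reached 1883 ± 224 CPM (log2 6.12, SE 0.20, adjusted p = 2.61e-09) and GABARAPL1 337 ± 11.2 CPM (6.29, SE 0.11, adjusted p = 2.06e-11), while MUC5AC fell to 0.313 ± 0.169 CPM (-6.20, SE 0.37, adjusted p = 1.94e-07). AKR1B10, HSPA6, GCNT3, HKDC1, GADD45G and HSPA1B rose by 6.41, 6.34, 6.22, 6.14, 5.77 and 5.73. NOG, ADGRF1, SMAD6, IGFBP1, FOXQ1, ATOH8 and SPRY1 changed by -5.21, -4.59, -4.42, -4.14, -3.92, -3.88 and -3.69.

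In each of these comparisons 14 of 32 lists passed, and 11 of them with an estimated correlation. Proteasome subunits rose in 31 of 33 cases with bortezomib and TM (median 1.44, adjusted p = 8.13e-29; adjusted p = 0.000604 with an estimated correlation) and in 31 with bortezomib and AMD3100 (1.38, adjusted p = 1.04e-28; adjusted p = 0.000814 with an estimated correlation). PSMC4, an ATPase of the regulatory particle, went from 200.1 ± 21.99 to 1197 ± 83.1 and 1142 ± 55.4 CPM. PSMB5, the subunit that bortezomib binds, rose from 269 ± 22.3 to 665 ± 95.4 (log2 1.30, adjusted p = 2.76e-06) and 593 ± 16.6 CPM (1.14, 9.5e-06). Heat shock genes rose in 16 and 18 of 19 cases (18 and 18 adjusted over the list alone; medians 1.47 and 1.504, adjusted p = 5.59e-28 and 1.85e-31; 0.000590 and 0.000405 with an estimated correlation). DNAJB1, a co-chaperone, went from 235 to 2799.8 and 2582 CPM and HSPB8 from 5.95 to 106 and 109. Of 21 ATF4 targets, 18 rose in either arm (medians 1.49 and 1.53, adjusted p = 7.63e-25 and 1.04e-28; 0.00621 and 0.00402 with an estimated correlation), such as the transcription factor ATF3 (3.80 to 167 and 145 CPM) and SESN2 (10.02 to 111 and 112). Chaperones of the endoplasmic reticulum rose in 13 and 14 of 18 cases and fell in 1 and 0 (medians 1.01 and 1.16, adjusted p = 3.66e-13 and 5.49e-16; 0.00168 and 0.00155 with an estimated correlation), for example HSPA5 from 511 to 4493 and 4722 CPM and HERPUD1 from 60.7 to 641 and 657. NRF2 targets had 16 rises and 1 fall among 20 in either arm (medians 1.27 and 1.31, adjusted p = 3.66e-13 and 1.67e-14; 0.00168 and 0.00144 with an estimated correlation). HMOX1, heme oxygenase, rose from 12.8 ± 0.403 to 63.9 ± 9.95 and 62.9 ± 4.50 CPM, and OSGIN1 by 3.52 and 3.46.

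Autophagy and lysosome genes rose in 15 of 20 cases in either arm (medians 0.88 and 0.86, adjusted p = 2.26e-15 and 7.54e-17; 0.00313 and 0.00214 with an estimated correlation), such as the ubiquitin-binding receptor SQSTM1 (225 to 2509 and 2222 CPM) and MAP1LC3B (73.2 to 258 and 271). Apoptosis genes had 11 and 10 rises and 3 and 2 falls among 20 (medians 1.18 and 0.93, adjusted p = 6.76e-08 and 3.21e-08; 0.00480 and 0.00391 with an estimated correlation). GADD45A went from 23.7 to 260.4 and 264 CPM and CDKN1A from 51.5 to 324 and 278. NF-κB targets had 11 rises and 2 falls among 17 in either arm (medians 1.56 and 1.497, adjusted p = 4.51e-05 and 1.44e-05; 0.0129 and 0.00989 with an estimated correlation), with the NF-κB subunit RELB going from 5.61 to 51.1 and 48.8 CPM and NFKB2 from 57.6 to 248 and 272. Hypoxia and glycolysis genes rose in 14 and 13 of 21 cases and fell in 3 and 2 (medians 0.77 and 0.63, adjusted p = 7.38e-05 and 0.000187; 0.0307 and 0.0407 with an estimated correlation). Here ADM rose by 2.11 and 2.11 while LDHA, lactate dehydrogenase, changed by -0.95 and -0.93. Cholesterol synthesis genes rose in 14 and 14 of 22 cases and fell in 1 and 2 (medians 0.51 and 0.67, adjusted p = 0.00315 and 0.00449; 0.0364 and 0.0407 with an estimated correlation), such as FDPS (1.27 and 0.97).

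MHC class I genes had 9 rises and 2 falls among 14 in either arm (medians 0.87 and 0.83, adjusted p = 0.00315 and 0.00403), a call lost with an estimated correlation (adjusted p = 0.0698 and 0.0690). HLA-E went from 175 to 459.9 and 405 CPM. B2M, the class I light chain, went from 142 ± 17.5 to 245 ± 28.4 and 201 ± 29.7 (adjusted p = 0.000468 and 0.00940; the second not called without bortezomib and AMD3100 replicate 2, 0.39). NLRC5, an activator of class I genes, fell from 16.4 to 4.94 and 5.20. Histones (6 and 5 rises among 9; medians 1.00 and 0.75, adjusted p = 0.00104 and 0.00403) lost the call in the same way (adjusted p = 0.0698 and 0.101 with an estimated correlation). Oxidative phosphorylation genes passed with bortezomib and TM, with 25 rises and 2 falls among 41 (median 0.499, adjusted p = 0.000938; adjusted p = 0.3002 with an estimated correlation). They did not pass with bortezomib and AMD3100, with 15 rises and 4 falls (median 0.26, adjusted p = 0.109). Metallothioneins and zinc transporters passed as a list with bortezomib and AMD3100, with 4 falls among 7 (median -0.81, adjusted p = 0.00654). With an estimated correlation the adjusted p was 0.131. With TM in place of AMD3100 the values were 3 falls, -0.59 and adjusted p = 0.0553; the direct comparison of these arms follows their other results. MT1E, a metal-binding protein, went from 134 ± 3.45 to 35.7 ± 2.06 and 25.2 ± 1.46 CPM and the zinc exporter SLC30A1 from 20.5 to 8.11 and 7.66. MT2A was at 617, 593 and 481 CPM (adjusted p = 0.745 and 0.0452; the second called with vehicle 3 left out, but not with any other 1 of the 6 libraries left out, -0.36 to -0.30, with median-of-ratios scaling, -0.32, or in DESeq2, -0.33). SLC31A1 rose from 42.8 to 78.6 and 74.9. CD274 was at 10.3 ± 1.51, 11.1 ± 3.41 and 14.98 ± 1.58 (adjusted p = 0.696 and 0.0570, though the second passed in DESeq2, 0.58, in limma-voom, 0.55, with median-of-ratios scaling, 0.58, without the low-count filter, 0.55, and with the 2 groups fitted alone, 0.53). CXCR4 had no counts in 8 of the 9 libraries and 6 counts in bortezomib and TM replicate 1. Cell cycle genes went both ways and did not pass as a list (5 and 5 rises, 11 and 9 falls among 32; medians -0.16 and -0.18, adjusted p = 0.491 and 0.489). RRM2 went from 508 to 1402 and 1498 CPM and the mitotic kinase AURKA from 142 to 54.9 and 63.8. Adjusted over each called list alone, further members passed with bortezomib and TM among MHC class I (9 rises and 3 falls), endoplasmic reticulum chaperone (14 and 1), ATF4 (18 and 1), apoptosis (12 and 3) and histone genes (6 and 2). The same held with bortezomib and AMD3100 among endoplasmic reticulum chaperone (15 rises and 0 falls), apoptosis (11 and 2) and cholesterol synthesis genes (15 and 2).

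Of 16498 genes tested, edgeR called 3981 higher and 4546 lower with bortezomib and TM, 8527 in all, and 3678 higher and 3997 lower with bortezomib and AMD3100, 7675 in all. The changes reached 2-fold for 4650 and 3879 of them. The balance of directions turned with the scaling: 4325 were higher and 4128 lower, and 3874 and 3772, with median-of-ratios factors, and 4358 and 4164, and 3964 and 3768, in DESeq2. The treated libraries also differed from vehicle in general measures: 22595 to 23228 genes had a count in the 6 treated libraries and 25020 to 25423 in the 3 vehicle libraries. Mitochondrial genes held 2.67% to 3.25% of counts against 3.94% to 4.06%, and ribosomal RNA 0.304% to 0.363% against 0.207% to 0.248%. Whether these differences bear on the calls was not tested.

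**Figure D2:**
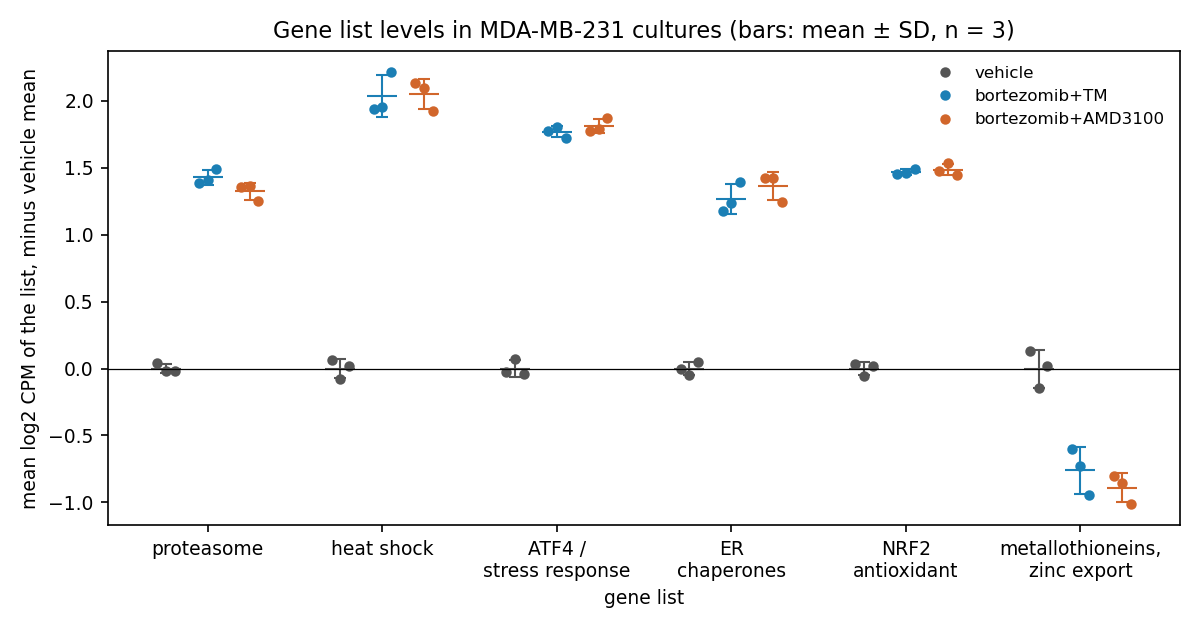
Mean log2 CPM of 6 gene lists in each of the 9 MDA-MB-231 libraries, less the mean of the vehicle libraries; points are libraries and bars are means ± SD of n = 3 per group. The 6 treated libraries lie above the 3 vehicle libraries for proteasome, heat shock, ATF4, endoplasmic reticulum chaperone and NRF2 genes, for which 31 of 33, 16 of 19, 18 of 21, 13 of 18 and 16 of 20 members rose with bortezomib and TM.

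The treated arms of MDA-MB-231 were also compared with each other, from TM to AMD3100 as the partner of bortezomib, and no single gene passed in edgeR. MT1E was at 35.7 ± 2.06 CPM with TM and 25.2 ± 1.46 with AMD3100 (log2 -0.504, SE 0.10, adjusted p = 0.344). PSMB5 was at 665 and 593 (0.680), B2M at 245 and 201 (0.569), MT2A at 593 and 481 (0.552, but called without bortezomib and TM replicate 3, -0.48) and CD274 at 11.1 and 14.98 (0.589). Metallothioneins and zinc transporters had a median of -0.082 (adjusted p = 0.138). Oxidative phosphorylation genes were lower with AMD3100 as a list (median -0.20 over 41, adjusted p = 8.47e-10; adjusted p = 0.356 with an estimated correlation), for example ATP5F1B, an ATP synthase subunit, at 2432 and 2055 CPM. Proteasome subunits were lower too (-0.13, 0.00173; adjusted p = 0.356 with an estimated correlation), a call lost without bortezomib and AMD3100 replicate 3 (-0.12). Collagens and lysyl oxidases were higher (0.19, 0.0215; 2 of 15 members adjusted over the list alone; adjusted p = 0.514 with an estimated correlation), a call lost without bortezomib and TM replicate 3 (0.11) or bortezomib and AMD3100 replicate 1 (0.25) or 3 (0.20). Beside the count of 0, 1464 genes had an unadjusted p under 0.05, DESeq2 called 64 and limma-voom 0, and edgeR called 183 without bortezomib and TM replicate 3.

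Tumours from mice given bortezomib with TM or with AMD3100 were compared with tumours from vehicle-treated mice, to ask what each combination changes in the tumour and the cells within it. Of all lists, B cell and T cell markers had the largest medians in either comparison. Cd8a, a marker of cytotoxic T cells, was at 18.4 ± 13.5 CPM with vehicle, 35.9 ± 21.8 with bortezomib and TM (log2 0.96, SE 0.71, adjusted p = 0.887) and 56.4 ± 36.8 with bortezomib and AMD3100 (1.61, SE 0.72, adjusted p = 0.634). Cd4 was at 8.71 ± 7.48, 34.98 ± 40.2 and 58.7 ± 56.7 CPM, the T cell kinase Lck at 22.2 ± 18.8, 57.9 ± 44.9 and 101 ± 89.6, and the B cell receptor protein Cd22 at 19.1 ± 13.9, 63.6 ± 64.7 and 90.7 ± 88.1. Gzmb, a killer cell protease, was at 15.1 ± 6.19, 15.3 ± 3.63 and 12.8 ± 1.36 CPM and Ifng, interferon-γ, at 1.13 ± 0.403, 1.88 ± 0.682 and 1.53 ± 0.507. The adjusted p-values of these and all other single genes missed 0.05.

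As a set, T cell markers had a median log2 change of 1.62 with bortezomib and TM and 2.41 with bortezomib and AMD3100 over 12 genes (adjusted p = 1.14e-06 and 8.76e-10; adjusted p = 0.469 and 0.588 with an estimated correlation). Their mean level against the vehicle mean was -0.22, -1.18 and 1.40 in vehicle tumours 1, 2 and 3, then 2.99, 1.61 and -0.013 with bortezomib and TM and 3.70, 0.23 and 2.67 with bortezomib and AMD3100. B and plasma cell markers had medians of 2.54 and 3.03 (0.00127 and 0.00121; adjusted p = 0.469 and 0.643 with an estimated correlation). Their mean levels were -1.72, -0.92 and 2.64 with vehicle, 5.09, 3.28 and -2.01 with bortezomib and TM and 5.09, -1.14 and 3.94 with bortezomib and AMD3100. CD8 and cytotoxic markers had medians of 0.53 and 0.65 (0.00275 and 0.00116; adjusted p = 0.469 and 0.643 with an estimated correlation). CD4 and regulatory T cell markers had 0.88 and 1.12 (4.07e-05 and 3.01e-06; adjusted p = 0.469 and 0.643) and NK cell markers 0.56 and 0.68 (0.00686 and 0.00122; adjusted p = 0.469 and 0.643), the second pair of values being with an estimated correlation. With bortezomib and TM, the CD8 list did not pass without vehicle 2 (0.19) or treated tumour 1 (0.29), the NK list without the same tumours (0.19 and 0.301), and the CD4 (0.35) and B cell (1.31) lists without treated tumour 1. With bortezomib and AMD3100 the CD8 list did not pass without vehicle 2 (0.46).

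Type I interferon response genes had the smallest adjusted p-values of all lists, with medians of 0.55 and 0.70 over 28 genes (6.15e-18 and 3.76e-24; adjusted p = 0.387 and 0.482 with an estimated correlation). With bortezomib and AMD3100, 11 of them passed adjusted over the list alone. Bst2 was at 204 ± 61.1, 248 ± 59.5 and 264 ± 12.4. The interferon-γ list had 0.34 and 0.22 (0.000125 and 0.00121; adjusted p = 0.469 and 0.643 with an estimated correlation), and did not pass without vehicle 2 in either comparison (0.077 and 0.031) or without the second AMD3100 tumour (0.26). MHC class I genes had 0.17 (0.00145; adjusted p = 0.469 with an estimated correlation; not called without vehicle 2, 0.056, or treated tumour 3, 0.10) and 0.14 (0.0843), with B2m at 1743 ± 263, 2148 ± 144 and 1903 ± 207 CPM. MHC class II genes had 0.13 (0.225) and 0.34 (0.00665; adjusted p = 0.645 with an estimated correlation; not called without vehicle 2, 0.0037). NF-κB targets had 0.27 and 0.296 (0.00156 and 0.0489; 1 and 0 of 20 adjusted over the list alone; adjusted p = 0.387 and 0.643 with an estimated correlation). The first of these calls was lost without vehicle 2 (0.17), and the second without vehicle 2 (0.067) or treated tumours 2 (0.080) or 3 (0.32) and with median-of-ratios scaling (adjusted p = 0.0525), without the low-count filter (0.28) or with the 2 groups fitted alone (0.27).

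Among myeloid and tumour cell genes, macrophage markers were lower as a list (-0.44 and -0.23 over 16, 8.25e-06 and 0.0195; adjusted p = 0.387 and 0.643 with an estimated correlation). Apoe was at 1569 ± 178, 1196 ± 323 and 1426 ± 518 CPM. In the AMD3100 comparison that call was lost without vehicle 3 (-0.081) or treated tumour 3 (-0.13). Neutrophil markers were lower too (-0.27 and -0.48, 0.00762 and 0.00598; adjusted p = 0.387 and 0.482 with an estimated correlation), a call lost with TM without vehicle 1 (-0.28) or treated tumour 3 (-0.14). Epithelial markers had -0.81 with bortezomib and AMD3100 (4 of 14 genes adjusted over the list alone, 6.37e-08; adjusted p = 0.482 with an estimated correlation) and -0.14 with bortezomib and TM (0.225). The keratin Krt8 was at 1109.6 ± 284, 793 ± 240.0 and 625 ± 70.4 CPM. Cholesterol synthesis genes had 0.498 and 0.20 (4.67e-16 and 0.0195; adjusted p = 0.387 and 0.699 with an estimated correlation). The second of these calls was lost without vehicle 2 (0.13) or treated tumour 2 (0.079).

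Proteasome genes, which rose in MDA-MB-231, had medians of -0.079 and -0.10 in the tumours (0.0339 and 0.00194; adjusted p = 0.804 and 0.699 with an estimated correlation). The first median ran from -0.15 to 0.052 with 1 tumour left out, its call being lost without vehicle 2 (-0.059) or vehicle 3 (-0.044) or with the 2 groups fitted alone (-0.072), and the second call was lost without vehicle 3 (-0.077) or treated tumour 1 (-0.054). Psmb5 was at 40.9 ± 3.02, 34.8 ± 5.41 and 33.2 ± 4.26 CPM (adjusted p = 0.887 and 0.634). Cxcr4 was at 26.2, 26.2 and 31.6 CPM, Cd274 at 70.1, 88.6 and 85.03, and Slc31a1 at 56.9, 60.6 and 54.9. Hmox1 was at 116, 129.6 and 120.3, Mt2 at 153, 160.2 and 144 and Hspa1a at 14.2, 15.1 and 14.4, with adjusted p-values of 0.887 or more with TM and 0.735 or more with AMD3100.

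In each of these comparisons 18 of 39 lists passed and none with an estimated correlation. edgeR called 0 of 15846 genes in either, beside 688 and 1144 genes at an unadjusted p under 0.05, while DESeq2 called 3 and 21 and limma-voom 0 and 0. The tumours also differed in general measures. Among counts of 1 to 20, even numbers made up 57.98% to 62.9% in the 6 treated tumours and 63.4% to 66.1% in the 3 vehicle tumours. Ribosomal RNA held 1.14% to 1.82% of counts with vehicle, 0.618% to 1.40% with bortezomib and TM and 0.912% to 1.71% with bortezomib and AMD3100. Whether these differences bear on the lists was not tested.

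**Figure D3:**
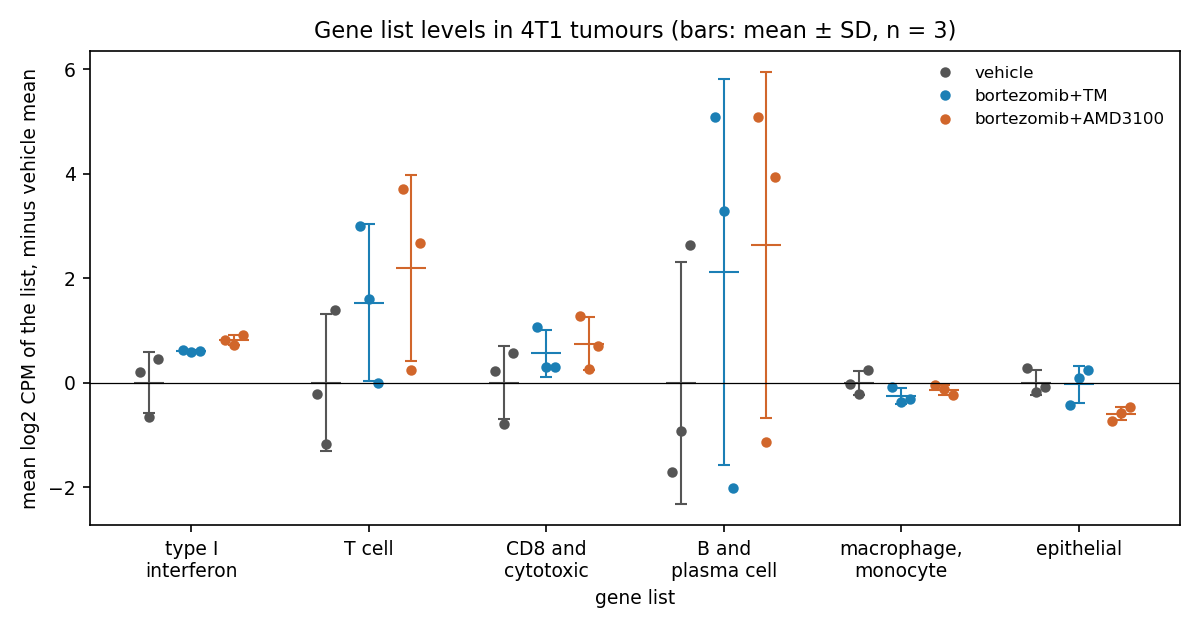
Mean log2 CPM of 6 gene lists in each of the 9 tumours from 4T1 cells, less the mean of the vehicle tumours; points are tumours and bars are means ± SD of n = 3 per group. T cell levels ran from -1.18 to 1.40 in vehicle tumours and from -0.013 to 3.70 in treated tumours, and 4 of the 6 treated tumours lay above all 3 vehicle tumours.

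Between the treated arms of 4T1, from TM to AMD3100 as the partner of bortezomib, edgeR called 0 genes, with 454 at an unadjusted p under 0.05, 4 called by DESeq2 and 0 by limma-voom. Epithelial markers had a median of -0.38 (1 of 14 adjusted over the list alone, 2.08e-07; adjusted p = 0.325 with an estimated correlation), with Krt8 at 793 CPM with TM and 625 with AMD3100. Endoplasmic reticulum chaperones had -0.19 (2.15e-06; adjusted p = 0.325 with an estimated correlation), with Hspa5 at 1846 and 1449 CPM, and cholesterol synthesis genes -0.29 (2.14e-08; adjusted p = 0.928 with an estimated correlation; not called without bortezomib and TM replicate 3, -0.079). Heat shock genes had -0.17 (3.65e-05; adjusted p = 0.928 with an estimated correlation), not called without TM tumour 2 (-0.095) or AMD3100 tumour 1 (-0.10). Type I interferon genes had 0.13 (0.0124; adjusted p = 0.928 with an estimated correlation), not called without TM tumour 1 (0.11) or AMD3100 tumour 3 (0.11). T cell markers had 0.81 (0.0382; adjusted p = 0.928 with an estimated correlation), from -0.072 to 1.70 with 1 tumour left out and not called without TM tumour 2 (0.68) or 3 (0.37) or AMD3100 tumour 3 (0.88). Cd8a was at 35.9 and 56.4 CPM (log2 0.65, SE 0.70, adjusted p = 0.996). Milk genes had -1.12 (0.01001; adjusted p = 0.325 with an estimated correlation), not called without TM tumour 1 (-0.65) or AMD3100 tumour 2 (-0.73) or without the low-count filter (-0.80).

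The paired arms of each dataset share their vehicle libraries, so their changes were compared against 10 simulated draws with no effect. In MDA-MB-231 the changes of the arms correlated across genes (Pearson r 0.912, Spearman rho 0.924), with 3330 genes higher in both arms where independent lists would share 888, 3526 lower in both where they would share 1101, and 0 called in opposite directions. With 1 library left out these were 2812 to 3218, 2879 to 3318 and 0 to 2. The covariance was 1.26 against 0.0588 simulated, a difference of 1.20, and the simulated r was 0.484. In 4T1 r was 0.780 and rho 0.635 (covariance 0.3002 against 0.0960, difference 0.204, simulated r 0.499). With 1 tumour left out r ran from 0.504 to 0.887. The lowest value, without bortezomib and TM replicate 1 (covariance 0.186), was close to the simulated r. In HCC1937 r was 0.222 and rho 0.143, below the simulated r of 0.502 (covariance 0.117 against 0.146, difference -0.0298). The simulated spread is that of a fit with AMD3100 replicate 1, which stands apart. The shortfall therefore cannot be read as less agreement than with no effect. Without the low-count filter r was 0.401, and with 1 library left out it was 0.126 to 0.375. Without AMD3100 replicate 1, r was 0.281 against 0.439 simulated (covariance 0.108 against 0.0601, difference 0.0481). Then 105 genes were higher in both arms where independent lists would share 32.4. Another 50 were lower in both where they would share 22.8, and 42 were called in opposite directions. Wherever a treated library was left out, as here, the other arm kept its changes and calls from the fit of all libraries. The simulation without AMD3100 replicate 1 left it out for both arms. Genes are not independent replicates, no split of 3 vehicle libraries leaves 2 for each arm, and part of the excess in r and in shared calls may come from the shared controls. The difference in covariance leaves out the simulated part of these controls. The simulation drew each gene independently, so it held no variation that many genes share between libraries. In 4T1, where lymphocyte markers varied together between tumours, such variation could also raise the covariance. The excess there is therefore not a measure of a treatment effect.

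Across the human lines, the TM arms (TM alone in HCC1937, with bortezomib in MDA-MB-231) had r 0.187 and rho 0.186 over 14680 genes. Without the low-count filter these were 0.0467 and 0.0695 over 32493 genes. Among the 14680, 218 genes were higher in both where independent lists would share 129, 362 lower in both where they would share 206, and 225 called in opposite directions. These numbers fell alike whichever 1 of the 6 vehicle and TM libraries of HCC1937 was left out. They were then 65 to 76 where 35.9 to 41.7 would be shared, 118 to 154 where 58.9 to 75.1 would be, and 60 to 67. Fewer HCC1937 genes were called in these fits, which kept AMD3100 replicate 1, while r stayed at 0.164 to 0.173. Without any 1 of the 6 compared MDA-MB-231 libraries they were 204 to 221, 307 to 376 and 189 to 224. CDKN1A and GADD45A were among the genes called higher in both. The AMD3100 arms had r 0.0192 and rho 0.0310. Without HCC1937 AMD3100 replicate 1 r was 0.00786, with 359 genes higher in both where 241 would be shared, 87 lower in both where 125 would be, and 424 called in opposite directions. The difference between the AMD3100 and TM arms was tested for a difference between the lines, where bortezomib is confounded with the line. edgeR called 625 of 21590 genes, 282 of them with a higher and 343 with a lower difference in MDA-MB-231, a balance that turned in several fits with 1 library left out (161 and 147 without HCC1937 TM replicate 1, for example). HMMR (log2 -3.12, adjusted p = 0.00022) and HSD17B8 (-2.94, 5.45e-05) were lower with TM than with AMD3100 in HCC1937 and differed in this test. The count was 1866 without HCC1937 AMD3100 replicate 1, 308, 268 and 298 without HCC1937 TM replicates 1, 2 and 3, 313 without bortezomib and TM replicate 2 in MDA-MB-231, and 363, 318 and 382 without bortezomib and AMD3100 replicates 1, 2 and 3.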

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

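The tests of GC content, of a stronger response and of the splits were set before their results were seen, and the other tests in this part were chosen after.

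HCC1937 AMD3100 replicate 1 stood apart from the other 8 libraries and moved most counts of that line. At matched depth, 20465 genes were expected to have a count, given the share of each gene in this library. That is 73.8% of the lowest other library, as a library of low complexity would give. GC content is open: its difference from the other AMD3100 libraries correlated with transcript GC content at rho -0.43, where vehicle and TM libraries reached 0.279 at most in size, but AMD3100 replicates 2 and 3 reached 0.368 and 0.457 against a mean that holds replicate 1. The SD of that difference across genes was 1.70 before and 1.60 after the trend with GC content and length was removed. It was 0.505 at most in vehicle and TM libraries (GC content was known for 17466 of 19461 genes). This argues against that trend as the whole cause. Bias of this kind is not excluded, because the trend was taken from the longest transcript of each gene and the SD also holds count noise. For a stronger response to AMD3100, r was -0.0455 between its change and that of the other AMD3100 libraries. This cannot exclude such a response, because replicate 1 differs so widely and the other libraries were set against vehicle replicate 3 alone. The AMD3100 changes were also small without replicate 1, with 82 of 1661 called genes reaching 2-fold.

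In MDA-MB-231, the treated libraries lined up with replicate 3 of each arm beside the other arm. The split that exchanges these libraries called 1862 genes where the labelled split called 0, which points to structure among the samples that the group labels do not hold. The difference along that split correlated with vehicle replicate 2 minus vehicle replicate 3 at r 0.397, against 0.106 for the labelled split. Variation between cultures that all groups share would give this, but so could differences between libraries in their preparation. That pair is the largest of 3: vehicle replicate 1 minus 2 gave -0.319 and 1 minus 3 gave 0.144 for the exchanged split, and -0.0727 and 0.0525 for the labelled split. Exchanged labels are open, since the same r 0.397 does not exclude them. Ribosomal RNA held 0.351% to 0.363% of counts in bortezomib and TM replicate 3 and bortezomib and AMD3100 replicates 1 and 2. It held 0.304% to 0.314% in the other treated libraries. Even numbers made up 61.7% to 62.8% and 58.9% to 61.6% of counts of 1 to 20 in these sets. They made up 57.8% in vehicle replicate 2 and 59.7% in vehicle replicate 3. Whether these measures bear on that split was not tested.

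In 4T1, lymphocyte markers differed between tumours. With bortezomib and AMD3100 the median of T cell markers was 2.64 above that of macrophage markers. This argues against a lower share of tumour cells with all other cell types rising alike. It cannot exclude a lower share along with a changed mix of the other cells. Mean epithelial marker levels were 0.27, -0.18 and -0.093 in vehicle tumours 1, 2 and 3. They were -0.43, 0.081 and 0.24 with bortezomib and TM and -0.73, -0.58 and -0.48 with bortezomib and AMD3100. Lymphoid tissue in some samples is open: with the B cell marker level in the fit, the median of the T cell markers with bortezomib and AMD3100 was 0.95 in place of 2.41. With bortezomib and TM it was 0.49 in that fit. Treatment is open as well, with 4 of 6 treated tumours above all 3 vehicle tumours. A section of each tumour stained for T and B cells would help to tell lymphoid tissue and treatment apart.

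With 10 splits of 6 libraries, no share under 0.1 can be reached, so they neither exclude nor bear out a chance division of the samples. The labelled split and the highest other split called 1376 and 0 genes in HCC1937 TM against vehicle, 1599 and 0 in AMD3100 against TM, 8527 and 1 in MDA-MB-231 bortezomib with TM and 7675 and 0 in bortezomib with AMD3100, so 1 of 10 splits called as many genes. In the other comparisons the labelled split called 0 and all 10 called as many. Among them the highest other split called 0 in HCC1937 AMD3100 against vehicle and in each 4T1 arm against vehicle, 1862 between the arms of MDA-MB-231 and 395 between the arms of 4T1. That 4T1 split sets bortezomib and TM replicate 1 beside bortezomib and AMD3100 replicates 1 and 3, the 3 tumours with the highest T cell marker levels.

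The difference between AMD3100 and TM arms differed between the human lines for 625 genes. Of 40 labellings 1, the real one, called that many (highest other 281). The labellings mixed TM and AMD3100 libraries within each line, so they also removed the difference between the arms in HCC1937. They bear on a lack of any difference between arms, and cannot exclude chance for a difference between the lines. Values are the difference in MDA-MB-231 minus that in HCC1937. They were -3.12 for HMMR (adjusted p = 0.00022), -2.94 for HSD17B8 (5.45e-05), 5.13 for SNORD3B-1 (0.00022), 6.21 for SNORD3C (0.00217) and 3.16 for SNORD3A (0.019). These 5 are among the 5 highest and 5 lowest genes picked by the rule between these arms of HCC1937. The remaining 5 of them did not pass, with TEX19 at -3.34 (0.0543), CELF5 at -7.43 (0.0928), ENTPD2 at -2.40 (0.147), LSMEM2 at 3.66 (0.0732) and DHRSX at 3.26 (0.0825).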

How the results depend on the processing

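Fits that leave out HCC1937 AMD3100 replicate 1 from a comparison it is not part of or along with a replicate block, and fits with GC content and length offsets, were chosen after the data were seen, and the others before.

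The number of called genes depended most on the fit in HCC1937, and the cause was not tested beyond the library that stands apart. For TM against vehicle, 1376 genes became 718 with a replicate block, 8336 with the 2 groups alone, 8318 with AMD3100 replicate 1 kept out, 8081 with a replicate block and that library kept out, and 2685 with GC content and length offsets. It was 424 at a 2-fold change, 491 at an adjusted p under 0.01 and 406 to 462 with 1 library left out. AMD3100 against vehicle gave 0 genes, but 161 without the low-count filter, 16 with DESeq2, 6 with offsets, 1030 with a replicate block and AMD3100 replicate 1 left out, and 0 to 1661 with 1 library left out. AMD3100 against TM gave 1599 genes, but 725 with a replicate block, 252 with the 2 groups alone, 6802 with a replicate block and AMD3100 replicate 1 left out, 2529 with DESeq2, 3216 with offsets, 519 at a 2-fold change, 430 at an adjusted p under 0.01, and 373 to 7442 with 1 library left out. Replicate numbers do not pair the libraries, since correlations between same-number libraries ran from -0.0374 to 0.0368 in HCC1937, -0.324 to 0.287 in MDA-MB-231 and -0.468 to 0.597 in 4T1.

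In MDA-MB-231, 4650 and 3879 genes changed at least 2-fold against vehicle. Between its arms DESeq2 called 64, the fit without the low-count filter 177, and fits with 1 library left out 0 to 183. In 4T1, DESeq2 called 3, 21 and 4 genes, the fit of bortezomib with AMD3100 and vehicle alone 1, and fits with 1 tumour left out 0 to 1 in each comparison with vehicle. The test between the human lines called 625, but 241 with a replicate block, 1481 with DESeq2 and 268 to 1866 with 1 library left out.

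The correlation of arms without the low-count filter was 0.401 in HCC1937, 0.645 in MDA-MB-231, 0.5698 in 4T1, 0.0467 for TM between lines and 0.00317 for AMD3100 between lines. With 1 library left out it ran from 0.126 to 0.375, 0.873 to 0.907, 0.504 to 0.887, 0.161 to 0.191 and 0.00576 to 0.0286. The scaling method moved none of these past its bound, and the cause of the other changes was not tested.

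Of 93 called lists, 69 lost the call with an estimated correlation, 3 with the groups alone, 2 with median-of-ratios scaling, 6 without the low-count filter and 3 with a replicate block. With AMD3100 replicate 1 left out along with a replicate block, 8 lost it while 11 kept it in HCC1937, and with that library kept out of TM against vehicle 1 lost it while 5 kept it. With 1 library left out the median changed sign for proteasome subunits in 4T1 bortezomib with TM (-0.15 to 0.052) and for T cell markers between the 4T1 arms (-0.072 to 1.70).

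Counted once in each comparison, 539 genes picked by the rule were run again, called or not. Of these, 56 lost the call with a replicate block, 47 with the groups alone, 36 without the filter, 11 with median-of-ratios scaling, 6 in limma-voom and 5 in DESeq2, while 0, 6, 8, 2, 4 and 8 gained it. With AMD3100 replicate 1 left out along with a replicate block 20 gained it, with that library kept out of TM against vehicle 5, and fits with 1 library left out lost it in 428 cases and gained it in 18. Some genes that did not pass changed sign with the setting. In HCC1937 TM against vehicle this was B2M with median-of-ratios scaling (0.0091), without the filter (0.036) and in DESeq2 (0.0096). In AMD3100 against vehicle it was TXN with median-of-ratios scaling (0.015), the groups alone (0.0049) and DESeq2 (0.0085), and MT2A without the filter (-0.00031), with a replicate block (-0.014) and in limma-voom (-0.028). With a replicate block and AMD3100 replicate 1 left out it was ENO1 (0.081), SLC3A2 (0.16), PSMB5 (0.15), B2M (0.016), SLC7A5 (0.11), FTL (0.12) and HMOX1 (0.071), and in AMD3100 against TM it was PSMB5 (0.048) and B2M (0.033). In MDA-MB-231 bortezomib and TM it was MT2A with median-of-ratios scaling (0.024) and DESeq2 (0.018). In 4T1 bortezomib and TM it was Cxcr4 without the filter (-0.020), with a replicate block (-0.10) and in limma-voom (-0.088), Mt2 with a replicate block (-0.22) and in limma-voom (-0.21), Col1a1 (-0.057) and Col3a1 (-0.062) in limma-voom, and Hspa1a with a replicate block (-0.023). In bortezomib and AMD3100 it was Hspa1a (-0.14 and -0.15 in the same fits), and between the 4T1 arms Mt2 in limma-voom (0.023).

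With 1 library left out in turn, the log2 change of further genes that did not pass took in 0. In HCC1937 AMD3100 against vehicle, this gave ENO1 from -0.10 to 0.080, CANX from -0.17 to 0.031, TXN from -0.052 to 0.046, SLC3A2 from -0.29 to 0.17, PSMB5 from -0.20 to 0.14, B2M from -0.26 to 0.0044 and MT2A from -0.16 to 0.21. There, it also gave SLC7A5 from -0.27 to 0.11, FTL from -0.51 to 0.13 and HMOX1 from -0.51 to 0.049. In HCC1937 AMD3100 against TM, this gave PSMB5 from -0.301 to 0.037 and B2M from -0.24 to 0.021. In MDA-MB-231 bortezomib and TM against vehicle, this gave CD274 from -0.15 to 0.26 and MT2A from -0.16 to 0.12. In MDA-MB-231 AMD3100 against TM as partner, this gave HSPA1A from -0.21 to 0.071 and HMOX1 from -0.16 to 0.061. In 4T1 bortezomib and TM against vehicle, this gave Cxcr4 from -0.41 to 0.23, Eomes from -0.026 to 0.81, Hmox1 from -0.083 to 0.39, Mmp9 from -0.69 to 0.013, Mt2 from -0.49 to 0.51, Col1a1 from -0.45 to 0.504 and Gzmb from -0.27 to 0.31. There, it also gave Col3a1 from -0.36 to 0.32, Arg1 from -0.27 to 0.18, Psmb4 from -0.20 to 0.0017, Hspa1a from -0.11 to 0.34, Lcn2 from -0.11 to 0.43, Nfkb1 from -0.051 to 0.16 and Cd74 from -0.27 to 0.38. In 4T1 bortezomib and AMD3100 against vehicle, this gave Apoe from -0.45 to 0.072, Cxcr4 from -0.035 to 0.46, Slc31a1 from -0.17 to 0.040, Psmd2 from -0.24 to 0.051, Atp5a1 from -0.24 to 0.0068, H2-Eb1 from -0.26 to 0.45 and Hmox1 from -0.060 to 0.14. There, it also gave Mt2 from -0.37 to 0.26, Gzmb from -0.53 to 0.050, Hspa1a from -0.43 to 0.35, Nfkb1 from -0.078 to 0.037, Cd74 from -0.030 to 0.62, Psmd3 from -0.17 to 0.045 and H2-Ab1 from -0.080 to 0.52. In 4T1 AMD3100 against TM as partner, this gave Srebf2 from -0.086 to 0.15, Cxcr4 from -0.036 to 0.66, Bst2 from -0.11 to 0.23, Cd6 from -0.0046 to 1.86, Csn3 from -0.53 to 0.090, Psmb5 from -0.20 to 0.031 and Lck from -0.12 to 1.54. There, it also gave Hsp90ab1 from -0.26 to 0.00026, Ifng from -0.60 to 0.028, Hmox1 from -0.35 to 0.13, Mt2 from -0.60 to 0.41 and Hspa1a from -0.54 to 0.26.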

Other observations

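CDKN1A, TXNIP, CCN2, HEG1 and SPRY4 in this part were chosen after their values were seen, as was the fit with the B cell marker level.

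In MDA-MB-231, copper handling genes went both ways with bortezomib and TM, 5 rising and 4 falling among 14 (median 0.022, adjusted p = 0.151). The copper chaperone of the mitochondrion COX19 went from 13.01 ± 0.519 to 70.3 ± 4.82 CPM, superoxide dismutase SOD1 from 157 ± 6.95 to 555 ± 15.6 and the metalloreductase STEAP3 from 81.9 ± 9.63 to 35.95 ± 1.83. With bortezomib and AMD3100 5 rose and 4 fell (median -0.050, a sign opposite to that of its test, adjusted p = 0.227). Type I interferon response genes had 11 and 9 rises and 5 and 4 falls among 25 (medians 0.41 and 0.31, adjusted p = 0.217 and 0.324), and the immunoproteasome list 2 and 1 rises and 0 and 1 falls (0.042 and -0.23, 0.729 and 0.933). Collagens and lysyl oxidases had 1 rise and 6 falls among 15 with bortezomib and TM (-0.35, 0.0730) and 1 and 4 with bortezomib and AMD3100 (-0.14, 0.256). In HCC1937 under TM, autophagy genes had 2 rises among 20 (0.19, 0.0752), oxidative phosphorylation genes 3 falls among 41 (-0.093, 0.113) and cholesterol synthesis genes 3 falls among 23 (-0.11, 0.225).

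In the 4T1 tumours, further lists passed without any single member passing over all genes, none with an estimated correlation. With bortezomib and TM these were endoplasmic reticulum chaperones (0.26, adjusted p = 4.07e-05; adjusted p = 0.387 with an estimated correlation), milk genes (1 of 4 adjusted over the list alone; 0.83, 0.00762; 0.387), fibroblast markers (0.19, 0.0122; 0.469), oxidative phosphorylation (-0.13, 0.000155; 0.541) and autophagy (-0.13, 0.00657; 0.469). With bortezomib and AMD3100 they were oxidative phosphorylation (-0.16, 3.01e-06; 0.643), autophagy (-0.10, 0.00116; 0.538), heat shock (-0.20, 0.00121; 0.689) and copper handling (-0.092, 0.0297; 0.482), the last value of each being the adjusted p with an estimated correlation. Hspa5 was at 1708 ± 208 CPM with vehicle and 1846 ± 214 with bortezomib and TM, the casein Csn3 at 6.80 ± 3.30 and 10.5 ± 4.40, and the lysosomal protease Ctsb at 1471 ± 76.98 and 1228 ± 112. With bortezomib and TM, calls were lost for fibroblast markers without vehicle 2 (0.20) or 3 (0.15) or treated tumour 2 (0.21), for oxidative phosphorylation without vehicle 3 (-0.061) or treated tumour 1 (-0.035), and for autophagy without vehicle 2 (-0.077). With bortezomib and AMD3100 they were lost for heat shock without treated tumour 1 (-0.10) and for copper handling without vehicle 2 (-0.11) or 3 (-0.12) or treated tumour 2 (-0.14).

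With the B cell marker level of each tumour in the fit, type I interferon genes had medians of 0.46 and 0.63 (adjusted p = 4.51e-17 and 1.28e-26, or 0.438 and 0.412 with an estimated correlation), and T cell markers 0.49 and 0.95 (2.68e-05 and 2.26e-13, or 0.606 and 0.412 with an estimated correlation). Cd8a changed by 0.42 (SE 0.44, adjusted p = 0.954) and 0.81 (SE 0.47, adjusted p = 0.935) in that fit, and edgeR called 0 genes in all 3 comparisons. Apart from the B cell markers themselves, calls were lost for proteasome genes (-0.023 and -0.043, adjusted p = 0.682 and 0.164), with bortezomib and TM for NK cell markers (0.39, 0.0548), and with bortezomib and AMD3100 for MHC class II (0.27, 0.0795) and heat shock genes (-0.094, 0.0818). Lists that passed only in this fit were endothelial markers (-0.44 and -0.54, 0.000649 and 2.18e-05), with bortezomib and TM hypoxia and glycolysis genes (0.11, 0.0186), and with bortezomib and AMD3100 MHC class I (0.14, 0.00940) and cell cycle genes (0.14, 0.00249). With an estimated correlation no list passed in it, the smallest adjusted p being 0.398.

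The smallest p-values in the test between the human lines belonged to CDKN1A (log2 2.94, adjusted p = 5.24e-06), TXNIP (-2.35), CCN2 (1.71), HEG1 (1.60) and SPRY4 (2.71).

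The first principal component held 59.9% of the variance in HCC1937 and set AMD3100 replicate 1 apart, while the second (17.3%) separated TM from the other libraries. In MDA-MB-231 the first held 61.2% and the second 12.04%, and in 4T1 50.98% and 11.6%. Replicate numbers did not pair libraries across groups: among 9 same-number pairs in each dataset, correlations of residuals over 0.1 were found in 0, 2 and 3.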
